A study of Mus musculus with 12 samples.

How the data were processed

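Liver RNA of male C57/Bl6J mice was measured by polyA RNA-seq in 12 libraries of 3 groups, with 4 libraries each. The groups were chow, a high-fat diet with 0.2% cholesterol by weight (HFD), and that diet with 0.006% SC-435 (HFD+ASBTi). SC-435 inhibits ASBT, the transporter that takes bile acids back up from the ileum and is encoded by Slc10a2. Per the labels' protocols, diets began at 4 weeks of age and lasted 16 weeks, livers were flash frozen, and libraries were made with the Illumina TruSeq RNA kit. No stranded counting is stated, so reads of overlapping and antisense genes could not be told apart. The labels do not say outright that each library is a separate animal, so p-values measure only the spread between these libraries, which may be technical.

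The authors' deposited table gives RPKM (reads scaled by transcript length and by library total) for 33763 RefSeq transcripts in each of the 12 libraries. Per the submitters' processing notes, Bowtie 0.12.7 and the genome build mm9 were used, and the counter, annotation release and read filters are not given in the sources used here. Of the 4 chow columns, 1 (headed C7) could be matched to its group but not to a single sample label, and is called chow C7. Beside the RPKM values, the authors' deposited table holds ratios of group means, unadjusted t-test p-values and group standard deviations. The standard deviations headed HFD+ASBTi and chow held each other's values in 25986 of 27035 transcripts where they differed, so none of these columns entered the tests.

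The length behind the RPKM values was worked out from low values. With the genomic span of the transcript (introns included) in the GRCm38 annotation, 85.4% to 91.2% of low values per library were whole multiples of 1 read within 0.05 of a read. With the spliced length, 12.5% to 14.6% were. The RPKM of a gene with long introns is therefore far below what its spliced length would give, and levels of different genes cannot be compared by RPKM, while folds of mean RPKM for 1 gene are not affected. The log2(RPKM + 0.5) values and the filter do depend on that length, so log2 changes of genes with long introns are shrunk more. From those steps, 1 read was worth 0.0755 to 0.112 RPM (reads scaled by library total alone), which gives about 8970000 to 13240000 reads per library. A span was found for 97.5% of the 23991 genes, and no coordinates are given because the builds differ. Read numbers given for genes are estimates from these steps and cover counting error only.

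For each gene the transcript with the highest mean was kept. Transcripts whose symbol had turned into a date (48) or that had none (2605) were named through their accession in the GRCm38 RefSeq gene table, which named 2589 of the latter and left 16 unnamed. The main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(RPKM + 0.5), for the 6325 genes with RPKM of at least 0.5 in at least 4 of the 12 libraries. All 12 libraries entered 1 model, which leaves 9 residual degrees of freedom. Genes were called at a two-sided Benjamini-Hochberg adjusted p under 0.05 in each of the 3 comparisons. Log2 fold changes are on the log2(RPKM + 0.5) scale and understate the change of low genes, while folds of means are on the RPKM scale. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

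The 30 gene lists were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the 25 lists with at least 5 tested members, and again with a correlation estimated per list. With the estimated correlation no list was called in any comparison. The lists were bile acid synthesis, bile acid transport and FXR signalling, cholesterol synthesis and uptake (SREBP2 targets), fatty acid synthesis (SREBP1c and ChREBP targets), LXR sterol efflux targets, PPARalpha targets, lipid droplet genes, lipoprotein assembly, glucose metabolism, acute phase response, interferon-stimulated genes, inflammatory cytokines, fibrosis, ER stress, CAR and PXR targets, NRF2 targets, oxidative phosphorylation, male-biased and female-biased liver genes, circadian clock and cell cycle. Markers of other cells and tissues were macrophages, T, B and NK cells, neutrophils, hepatocytes, cholangiocytes, endothelium, red blood cells, adipose tissue, and pancreas with intestine.

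The named genes followed 4 parts of a rule. These were the 6 largest higher and 6 largest lower log2 fold changes among called genes whose groups did not overlap and whose mean was at least 1 RPKM in 1 of the groups; up to 4 called members of each list that was called or had at least 1/3 of its members called; a panel of 25 genes, called or not, of which 20 passed the filter and some are not reported here; and up to 6 genes per direction among those called in HFD against chow and called the opposite way in HFD+ASBTi against HFD. The groups, tests, lists, naming rule and 13 alternatives were fixed before the data were examined. The alternatives covered the pseudocount, the filter on low values, scaling between libraries, the samples in the fit, library weights, robust variance estimation, a fold minimum, the list correlation, the replicate number as a block and leaving out each library. A further 7 alternatives were added after seeing the data.

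The test was checked on simulated data made from the 6325 genes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. In HFD against chow, 91% of the genes changed by 1 and 97% of those changed by 2 were recovered, and 4.57% of the calls were unchanged genes. In HFD+ASBTi against HFD these were 90%, 96% and 3.63%, and in HFD+ASBTi against chow 93%, 98% and 7.28%. Of 200 genes changed by a log2 of 2 and returned, 96.5% were found. Changes were set on the log2 scale of the test, where low genes need a larger fold. These shares are averages over simulated genes, not the chance of finding a given inhibitor effect. In HFD+ASBTi against HFD, Cyp7a1 and Scd1 had log2 changes of 1.28 and -1.04 and were not called. Their SEs were 0.288 and 0.526, against a median of 0.103. In that comparison 1 gene with an absolute log2 change of at least 1 was called. How spread shared by many genes of a library changes these shares was not tested. Libraries of 1 group differed by more than counting noise in every pair (chi-square per gene 5.57 to 59.6), which does not tell separate animals from repeat libraries of 1 liver.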

Results

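Liver RNA was compared between 4 libraries each from mice on chow, on a high-fat diet with added cholesterol (HFD), and on that diet with SC-435, an inhibitor of the ileal bile acid transporter ASBT (HFD+ASBTi). The design addresses what the diet does to liver RNA, what the inhibitor does on top of it, and how much of the diet change remains with the inhibitor. Estimated depth was 10670000 to 11350000 reads per chow library, 10310000 to 13240000 per HFD library and 8970000 to 11260000 per HFD+ASBTi library. The top 10 genes held 21.3% to 26.9% of the RPKM sum of a library. Within a group, log2 values of 2 libraries correlated across genes at 0.979 to 0.987 for chow, 0.976 to 0.983 for HFD and 0.975 to 0.986 for HFD+ASBTi; genes are not independent replicates.

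HFD livers held more RNA of several genes for making and storing lipid than chow livers. Srebf1, the transcription factor that drives fatty acid synthesis, rose 6.10-fold, from 1.62 ± 0.185 to 9.90 ± 0.286 RPKM (SD, n = 4 each; limma adjusted p = 1.80e-04). Apoa4, an apolipoprotein of triglyceride-rich particles, rose 18.1-fold, from 51.0 ± 17.2 to 923 ± 367 RPKM (limma adjusted p = 3.92e-04). G0s2, an inhibitor of triglyceride hydrolysis, rose 3.57-fold, from 30.1 ± 6.27 to 107 ± 41.1 RPKM (limma adjusted p = 0.00302). Cidec, a lipid droplet protein, rose 7.83-fold to 3.57 ± 1.99 RPKM, and Cd36, a fatty acid uptake receptor, rose 4.19-fold to 1.15 ± 0.262 RPKM (limma adjusted p = 0.0128 and 0.00325). Plin5, a lipid droplet protein of oxidative tissues, fell 2.57-fold to 3.08 ± 0.523 RPKM (limma adjusted p = 0.00699). Of 14 tested lipid droplet and PPARgamma targets, 7 rose, 1 fell and 6 were not called, with 10 called when adjusted over the list alone. The list was higher by camera (median log2 change 0.43, adjusted p = 0.00897), with adjusted p = 0.570 with an estimated correlation.

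Among 19 tested fatty acid synthesis genes, 4 rose, 1 fell and 14 were not called, with 10 called when adjusted over the list alone. Fads2, a fatty acid desaturase, rose 4.16-fold to 5.27 ± 1.71 RPKM (limma adjusted p = 0.00306). Lpin1, a phosphatidate phosphatase, fell 4.19-fold to 0.993 ± 0.406 RPKM (limma adjusted p = 0.0279), and its call ended without chow 1, 2 or 4 or HFD 1, 2 or 3 (adjusted p 0.0531 to 0.0755). Fasn (log2 change 0.94, adjusted p = 0.217) and Scd1 (1.19, adjusted p = 0.163), enzymes of fatty acid synthesis and desaturation, did not pass the test. The list was higher by camera (median 0.59, adjusted p = 0.0136), with adjusted p = 0.651 with an estimated correlation. Of 8 tested LXR sterol efflux targets, 4 rose and 4 were not called, with 6 called when adjusted over the list alone. Abcg5 and Abcg8, which together export sterols into bile, rose 1.93-fold to 4.52 ± 0.515 RPKM and 1.81-fold to 6.05 ± 0.972 RPKM (limma adjusted p = 0.00806 and 0.0101). Abca1, a cholesterol efflux transporter, rose 1.48-fold to 0.590 ± 0.0640 RPKM (limma adjusted p = 0.0284), a call that ended without chow 1, 2 or 4 or HFD 2, 3 or 4 (adjusted p 0.0582 to 0.0774). The LXR list was higher by camera (median 0.32, adjusted p = 0.0146), with adjusted p = 0.442 with an estimated correlation. Its call ended with no filter on low values (adjusted p = 0.0644) and with a mean of at least 1 RPKM as the filter (0.0544).

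Of 34 tested PPARalpha targets and fatty acid oxidation genes, 8 rose, 2 fell and 24 were not called, with 15 called when adjusted over the list alone. This list was not called by camera (median 0.20, adjusted p = 0.0597), and was called without chow C7, chow 4, HFD 1 or HFD 4 (adjusted p 0.0115 to 0.0444). Cpt1a, which carries fatty acids into mitochondria, was not called (log2 change 0.29, adjusted p = 0.128), except without HFD 1 (adjusted p = 0.00873). Of 26 tested SREBP2 targets, 2 rose, 2 fell and 22 were not called, with 5 called when adjusted over the list alone (median -0.14, adjusted p = 0.140). The SREBP2 list was called without chow 2 or HFD 3 (adjusted p 0.0134 to 0.0374). Sqle, squalene epoxidase, had a log2 change of -0.64 (limma adjusted p = 0.162). Of 16 tested lipoprotein genes, 2 rose, 1 fell and 13 were not called, with 3 called when adjusted over the list alone (median 0.11, adjusted p = 0.608).

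**Figure D1:**
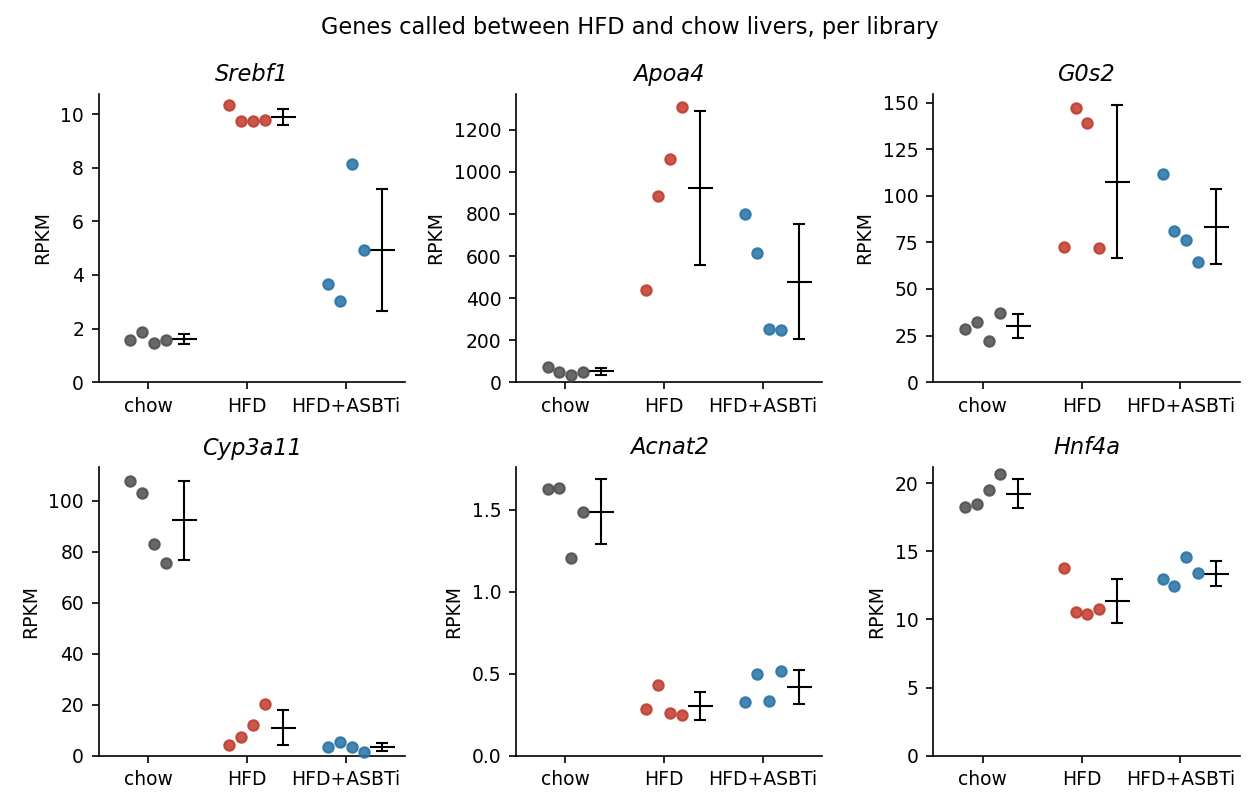
RPKM of 6 genes called between HFD and chow, 1 point per library, with the group mean and SD beside the points (n = 4). The HFD values of Srebf1, Apoa4 and G0s2 all lie above the chow values, and those of Cyp3a11, Acnat2 and Hnf4a all lie below them.

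HFD livers also held less RNA of several drug-metabolising enzymes. Cyp3a11, a main drug-oxidising cytochrome, fell 8.48-fold, from 92.3 ± 15.5 to 10.9 ± 6.90 RPKM (SD, n = 4 each; limma adjusted p = 0.00130). Cyp2c29 fell 3.12-fold to 4.93 ± 2.31 RPKM, Cyp3a25 fell 2.58-fold to 14.5 ± 3.20 RPKM, and Gadd45b, a stress response gene, fell to 0.311 ± 0.173 RPKM (log2 change -1.56) (limma adjusted p = 0.00840, 0.00844 and 2.65e-04). Of 18 tested CAR and PXR targets, 8 fell and 10 were not called, and 8 were called when adjusted over the list alone. The list was lower by camera (median -0.52, adjusted p = 5.12e-04), with adjusted p = 0.442 with an estimated correlation. The Cyp3a and Cyp2c genes have close copies, and how the counting split shared reads is not given.

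Among 17 tested bile acid synthesis genes, 2 rose, 5 fell and 10 were not called, with 8 called when adjusted over the list alone. Acnat2, an acyltransferase, fell 4.88-fold, from 1.49 ± 0.199 to 0.305 ± 0.0859 RPKM, and its close copy Acnat1 fell 1.79-fold to 7.04 ± 1.44 RPKM (limma adjusted p = 8.03e-05 and 0.0104). Scp2, a peroxisomal thiolase and sterol carrier, rose 1.49-fold to 19.1 ± 1.33 RPKM (limma adjusted p = 0.0126). Cyp8b1, the enzyme that makes cholic acid, fell 1.92-fold to 134 ± 25.6 RPKM (limma adjusted p = 0.0494), and its call ended without any 1 of the chow or HFD libraries or HFD+ASBTi 1 or 3 (adjusted p 0.0518 to 0.12). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 6.10 ± 1.09 against 8.07 ± 2.92 RPKM (limma adjusted p = 0.489), and Cyp7b1 had a log2 change of -0.16 (adjusted p = 0.696). The list was not called (median -0.16, adjusted p = 0.0635), except without HFD 1 (adjusted p = 0.0426). Of 12 tested bile acid transport and FXR signalling genes, 2 fell and 10 were not called, and 2 were called when adjusted over the list alone (median -0.05, adjusted p = 0.169). Fgfr4, the receptor for the ileal hormone FGF15, fell 1.54-fold to 0.733 ± 0.0880 RPKM (limma adjusted p = 0.00492). Nr0b2, Slc10a1 and Abcb11, a bile acid-induced repressor and the uptake and export transporters of hepatocytes, had log2 changes of 0.22, -0.13 and -0.31 (limma adjusted p = 0.622, 0.697 and 0.0982). Abcb11 was called without HFD 1 (adjusted p = 0.0492).

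Some genes of secreted liver proteins and of hepatocyte identity fell in HFD. Fga, the fibrinogen alpha chain, fell 1.91-fold, from 352 ± 38.8 to 185 ± 35.8 RPKM (SD, n = 4 each; limma adjusted p = 0.0126). Hnf4a, a transcription factor of hepatocyte identity, fell 1.69-fold, from 19.2 ± 1.08 to 11.3 ± 1.60 RPKM (limma adjusted p = 0.00126). Of 23 tested acute phase genes, 5 fell and 18 were not called, with 7 called when adjusted over the list alone. Of 19 tested hepatocyte markers, of which Fga and Fgb are also in the acute phase list, 5 fell and 14 were not called, with 7 called when adjusted over the list alone. Both lists were lower by camera (medians -0.59 and -0.17, adjusted p = 1.70e-04 and 0.00161), with adjusted p = 0.570 and adjusted p = 0.492 with an estimated correlation. Fgb, the fibrinogen beta chain, fell 1.62-fold to 157 ± 32.4 RPKM (limma adjusted p = 0.0257), a call that ended without chow 2, C7 or 4 or HFD 2 or 3 (adjusted p 0.0614 to 0.0723). Of 16 tested glucose metabolism genes, 3 rose, 3 fell and 10 were not called, with 7 called when adjusted over the list alone (median -0.00, mean -0.33, adjusted p = 0.656). Gys2, liver glycogen synthase, rose 1.93-fold to 2.31 ± 0.498 RPKM (limma adjusted p = 0.0126). G6pc and Pck1, enzymes of glucose production, fell 3.23-fold and 1.94-fold (limma adjusted p = 0.0285 and 0.0192). The G6pc call ended without chow 1, 2 or 4 (adjusted p 0.0551 to 0.0750), and the Pck1 call without chow 1 or 2 or HFD 2 or 3 (0.0525 to 0.0547).

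Several interferon-stimulated genes rose in HFD. Psmb9 and Psmb8, subunits of the immunoproteasome, rose 2.64-fold to 1.82 ± 0.242 RPKM and 1.68-fold to 4.49 ± 0.925 RPKM (SD, n = 4 each; limma adjusted p = 0.0124 and 0.00632). Ifit3, an antiviral protein, rose 3.39-fold to 2.39 ± 0.463 RPKM (limma adjusted p = 0.0203), and its call ended without chow 1 or 2 (adjusted p 0.0559 to 0.0607). Of 13 tested interferon-stimulated genes, 5 rose and 8 were not called, with 12 called when adjusted over the list alone. The list was higher by camera (median 0.64, adjusted p = 1.85e-05), with adjusted p = 0.442 with an estimated correlation. Of 12 tested macrophage and Kupffer cell markers, 2 rose and 10 were not called, with 2 called when adjusted over the list alone, and the list was not called (median 0.17, adjusted p = 0.307). Without chow C7, the chow library with the highest macrophage and interferon medians, the macrophage list was called (adjusted p = 0.00654). Cd68, a macrophage lysosomal protein, rose 1.93-fold to 2.08 ± 0.479 RPKM (limma adjusted p = 0.0202), a call that ended without chow 1, 2 or 4 or HFD 2 (adjusted p 0.0506 to 0.0607). Of 6 tested inflammatory cytokine genes none was called by limma, with 2 called when adjusted over the list alone (median 0.17, adjusted p = 0.441). None of 20 T, B and NK cell markers and none of 10 neutrophil markers passed the filter on low values, so these lists had no test.

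Lists of red blood cell and adipose markers were called higher in HFD. Of 6 tested red blood cell markers, the 4 globin entries rose and 2 were not called, with 4 called when adjusted over the list alone. Hbb-b1 rose 3.71-fold, from 16.6 ± 13.1 to 61.6 ± 20.6 RPKM (SD, n = 4 each; limma adjusted p = 0.0136), or 5.97-fold without chow 4. The globin entries share reads, so they are uncertain as separate genes. The red blood cell list was higher by camera (median 1.95, adjusted p = 0.00897), with adjusted p = 0.492 with an estimated correlation. With RPM in place of RPKM, an alternative added after seeing the data, its median was 0.14 (adjusted p = 0.0701); Hbb-b1 and Hbb-b2 had no span and were left out there, so members and scale changed at once. Of 5 tested adipose tissue markers, 3 rose and 2 were not called, with 3 called when adjusted over the list alone. Cidec and Lipe are also in the lipid droplet list. Lipe, hormone-sensitive lipase, rose 1.81-fold to 1.47 ± 0.261 RPKM (limma adjusted p = 0.0111). Cfd, the fat cell product adipsin, rose 20.5-fold, from 0.195 ± 0.358 to 4.01 ± 2.97 RPKM (limma adjusted p = 0.0188), a call that ended without chow 1 or 2 or HFD 2 or 3 (adjusted p 0.0524 to 0.0552). The Cfd fold depends on chow C7, at 0.731 RPKM against 0 to 0.0511 in the other chow libraries, and without it is 235.3-fold against a mean near 0. The adipose list was higher by camera (median 0.59, adjusted p = 0.0102), with adjusted p = 0.442 with an estimated correlation. Both tested members of the pancreas and intestine list rose, namely Fabp2, an intestinal fatty acid binding protein, 4.30-fold to 14.7 ± 3.08 RPKM and Cela2a, an elastase, 1.39-fold to 0.744 ± 0.0365 RPKM (limma adjusted p = 1.11e-04 and 0.0122), with 2 called when adjusted over the list alone.

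Of 15 tested circadian clock genes, 4 rose and 11 were not called, with 7 called when adjusted over the list alone. Dbp, a clock output gene, rose 2.47-fold, from 8.91 ± 2.80 to 22.0 ± 2.61 RPKM (SD, n = 4 each; limma adjusted p = 0.00563). Wee1, a clock-controlled cell cycle kinase, rose 3.80-fold to 0.553 ± 0.0786 RPKM and Per2, a repressor of the clock, rose 2.34-fold to 0.738 ± 0.0670 RPKM (limma adjusted p = 0.0136 and 0.0137). The clock list was higher by camera (median 0.29, adjusted p = 0.0140), with adjusted p = 0.570 with an estimated correlation. Its call ended with no filter on low values (adjusted p = 0.115) and with a mean of at least 1 RPKM as the filter (0.334). Chow C7 stood apart from the other chow libraries in Arntl, a core clock activator, at 6.25 RPM against 1.31 to 2.03 RPM. Every HFD library lay outside the chow values for Arntl, at 0.377 to 1.07 RPM, and for Per3, a clock repressor, at 37.2 to 56.5 RPM against 7.84 to 25.1 RPM, so a difference in clock phase stays open for this comparison too. Among 5 tested cell cycle genes, 2 rose and 3 were not called, with 2 called when adjusted over the list alone (median 0.00, adjusted p = 0.656). Ccnd1, cyclin D1, rose 7.81-fold to 3.06 ± 2.55 RPKM (limma adjusted p = 0.00779), with 6.87 RPKM in HFD 4 and 1.54 to 2.14 RPKM in the other HFD libraries, and rose 4.57-fold without HFD 4.

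Of 25 tested ER stress genes, 7 fell and 18 were not called, with 10 called when adjusted over the list alone. The ER stress list was not called (median 0.03, test direction lower, adjusted p = 0.140), except without chow 4 or HFD 1 (adjusted p 0.0321 to 0.0484). Ddit3, a stress-induced transcription factor, had a log2 change of 0.09 (limma adjusted p = 0.510). Of 9 tested fibrosis genes 1 fell, with 1 called when adjusted over the list alone (median 0.21, test direction lower, adjusted p = 0.903). These are 9 of 38 fibrosis genes, so most had no test. On the RPM scale, an alternative added after seeing the data, the list had 30 members and was called higher. Of 17 tested NRF2 targets 2 rose, with 2 called when adjusted over the list alone (median -0.02, mean 0.03, adjusted p = 0.903). Of 44 tested oxidative phosphorylation genes 3 rose, with 0 called by limma when adjusted over the list alone (median 0.09, adjusted p = 0.386). Of 19 tested male-biased liver genes, 2 rose, 3 fell and 14 were not called, with 6 called when adjusted over the list alone (median -0.13, adjusted p = 0.656). Of 5 tested endothelial markers, 3 tested female-biased genes and 1 tested cholangiocyte marker none was called by limma, with 0, 0 and 1 called when adjusted over the list alone. The endothelial list had a median of -0.16 (adjusted p = 0.213).

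Further genes with large changes had no list. Serpina7, thyroxine-binding globulin, rose 6.02-fold to 7.11 ± 2.59 RPKM and Rnf186, a ubiquitin ligase, rose 4.91-fold to 10.2 ± 0.906 RPKM (SD, n = 4; limma adjusted p = 0.00432 and 6.41e-04). Enho, which encodes the secreted peptide adropin, fell 7.87-fold to 0.805 ± 0.796 RPKM and Camk2b, a calcium-dependent kinase, fell 5.28-fold to 2.29 ± 0.266 RPKM (limma adjusted p = 0.00282 and 0.00490), and the Enho fold was 15.5 without HFD 4. Mir122a, the precursor of the main liver microRNA, was listed at 0 in the 4 HFD libraries and at 1.39, 4.26, 6.67 and 4.2 RPKM in the chow libraries (limma adjusted p = 0.0102), which rests on 1 to 5 estimated reads per chow library. The Mir1906-1 and Mir1906-2 entries share reads and fell 4.70-fold to 2.37 ± 3.31 RPKM (limma adjusted p = 0.0391), on 0 to 10 estimated reads per library, or 15.02-fold without HFD 2. Their call ended without any 1 chow library or HFD 1, 3 or 4 (adjusted p 0.0692 to 0.0905). Of the panel genes below the filter, mean RPKM in chow and HFD was 0.0736 and 0.219 for Slc10a2, 0.0661 and 0.133 for Pparg, 0.0175 and 0.121 for Tnf, 0.0240 and 0.340 for Ccl2, and 0.0483 and 0.149 for Col1a1.

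In all, limma called 766 of 6325 genes between HFD and chow, 484 higher and 282 lower, and 1813 had an unadjusted p under 0.05. Camera called 10 of 25 lists, 7 higher and 3 lower. In the authors' deposited table, 5122 of 27361 transcripts had an unadjusted p under 0.05 for this ratio. The higher and lower counts were 442 and 387 with median-of-ratios scaling, 358 and 339 with equal RPKM sums, and 426 and 384 with quantile normalization. The count of genes was 494 without chow 1, 458 without chow 2, 488 without HFD 2 and 475 without HFD 3.

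**Figure D2:**
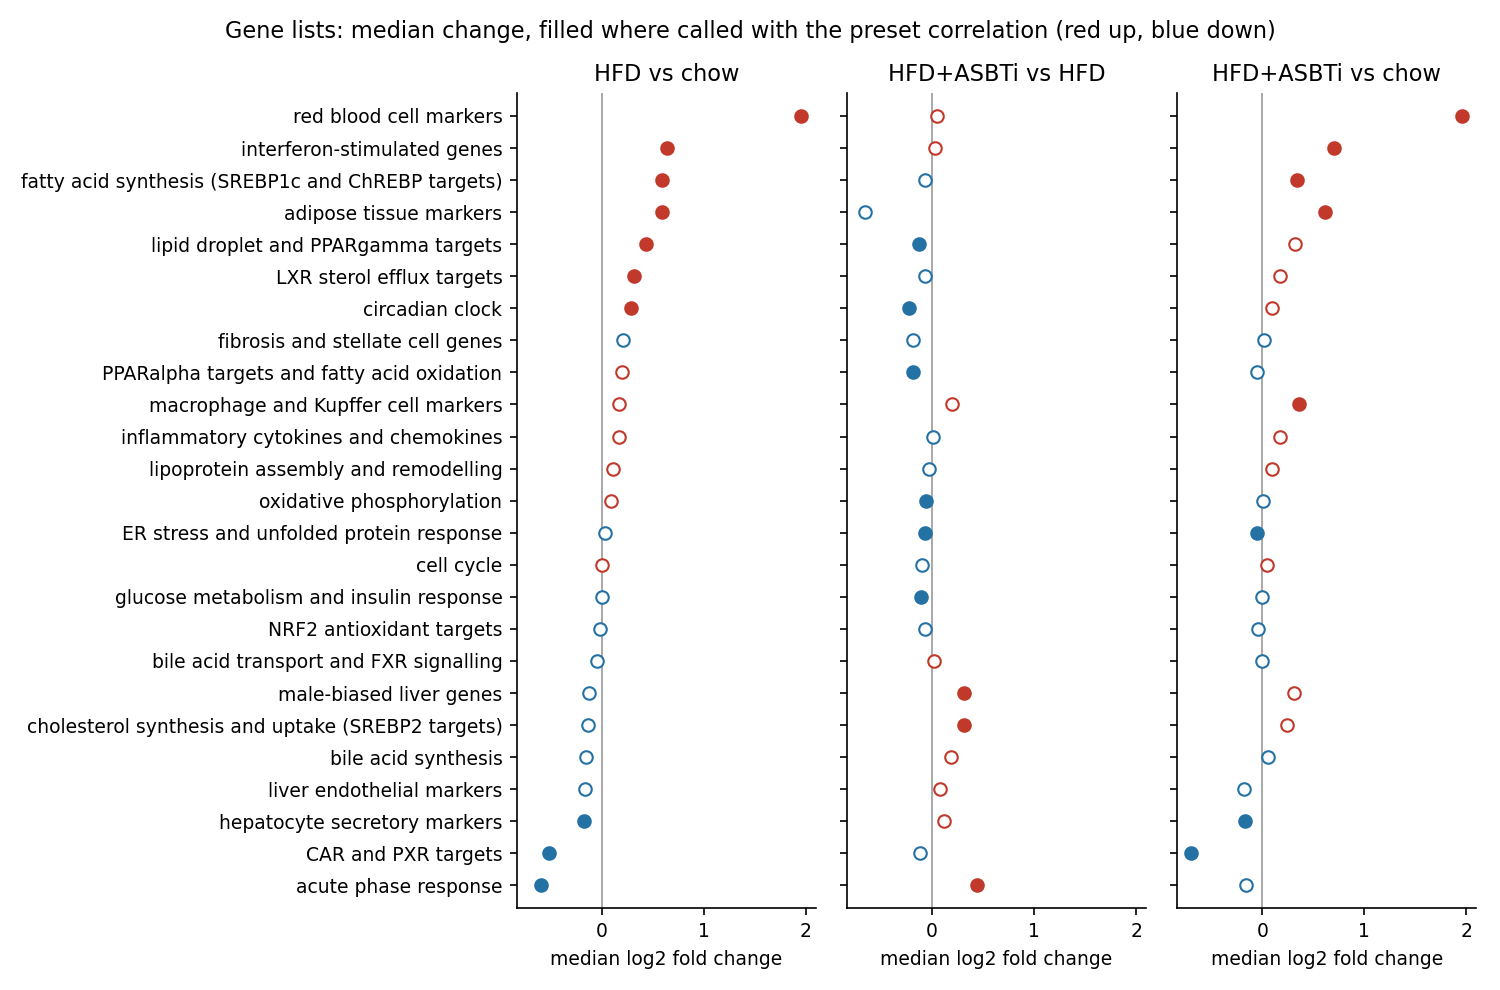
Median log2 fold change of each gene list with at least 5 tested members in the 3 comparisons, with the vertical line at 0. Filled points mark lists called by camera with the preset correlation and open points lists not called, red where the test direction was higher and blue where it was lower. Of the 25 lists, 10, 9 and 8 were called.

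Few single genes were called with the inhibitor. In HFD+ASBTi, Fgfr4, the receptor for the ileal hormone FGF15, rose 1.65-fold, from 0.733 ± 0.0880 to 1.21 ± 0.0792 RPKM (SD, n = 4 each; limma adjusted p = 0.0452). Bmp1, a procollagen protease, rose 1.80-fold to 1.69 ± 0.222 RPKM (limma adjusted p = 0.0466). The noncoding RNA 4931408D14Rik fell 4.34-fold, from 5.73 ± 2.46 to 1.32 ± 0.197 RPKM, and Maff, a small Maf transcription factor, fell 3.04-fold to 0.276 ± 0.0763 RPKM (limma adjusted p = 0.0284 for each). Pla2g6, a phospholipase, fell 1.88-fold to 0.516 ± 0.0830 RPKM, and Mmadhc, a vitamin B12 handling protein, fell 1.32-fold to 1.32 ± 0.0327 RPKM (limma adjusted p = 0.0466 for each). These 6 genes, 2 higher and 4 lower, were all that limma called of 6325, and 586 had an unadjusted p under 0.05. In the authors' deposited table, 1573 of 27309 transcripts had an unadjusted p under 0.05 for this ratio. Each call ended without at least 6 of the 12 libraries taken 1 at a time, with adjusted p up to 0.0910 for 4931408D14Rik, 0.115 for Maff, 0.163 for Fgfr4, 0.168 for Bmp1, 0.172 for Pla2g6 and 0.186 for Mmadhc. The count was 1 without chow 2, chow 4, HFD 2 or HFD 3, 2 without HFD 1, 3 without HFD 4, and 0 by limma without HFD+ASBTi 1, 2 or 4. With HFD+ASBTi 1 and 2 left out together limma called 0 genes, and with HFD+ASBTi 3 and 4 left out it called 121, the 6 among them; both alternatives were added after seeing the data, so the count depends on which 2 libraries stand for the group. Without each of the 12 libraries, the Mmadhc and Pla2g6 calls ended. The Bmp1 call was kept without chow 1 and HFD+ASBTi 3, and the Fgfr4 call without chow 1 and chow C7. The 4931408D14Rik call ended without chow 2, chow 4, HFD 1 or HFD+ASBTi 1, 2 or 4, and the Maff call without HFD 1, 2 or 3 or HFD+ASBTi 1, 2 or 4.

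Among bile acid and sterol genes, Cyp7a1, Srebf1 and Abcg5 did not pass the test although the libraries of the 2 groups did not overlap. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 16.3 ± 6.78 RPKM in HFD+ASBTi and 6.10 ± 1.09 in HFD, with each of the 4 libraries above the highest HFD library (SD, n = 4 each; log2 change 1.28, limma adjusted p = 0.241). Srebf1 had 4.94 ± 2.27 against 9.90 ± 0.286 RPKM and Abcg5 had 2.33 ± 0.631 against 4.52 ± 0.515 RPKM, with every HFD+ASBTi library below the lowest HFD library (limma adjusted p = 0.232 and 0.132). Without HFD+ASBTi 3, both fell (limma adjusted p = 0.00984 and 0.0256). Cyp8b1, Cyp7b1 and Abcb11 had log2 changes of 0.71, 0.32 and 0.28 (limma adjusted p = 0.453, 0.711 and 0.458), and Nr0b2, Slc10a1 and Abca1 of -0.24, 0.15 and -0.11 (adjusted p = 0.819, 0.857 and 0.652). Of 17 tested bile acid synthesis genes limma called 0 over all genes, and 1, Cyp7a1, was called higher when adjusted over the list alone. The list was not called by camera (median 0.18, adjusted p = 0.0899), except without HFD+ASBTi 3 (adjusted p = 0.0278). Of 12 tested bile acid transport and FXR signalling genes, Fgfr4 rose and 11 were not called, with 1 called when adjusted over the list alone (median 0.02, adjusted p = 0.655).

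**Figure D3:**
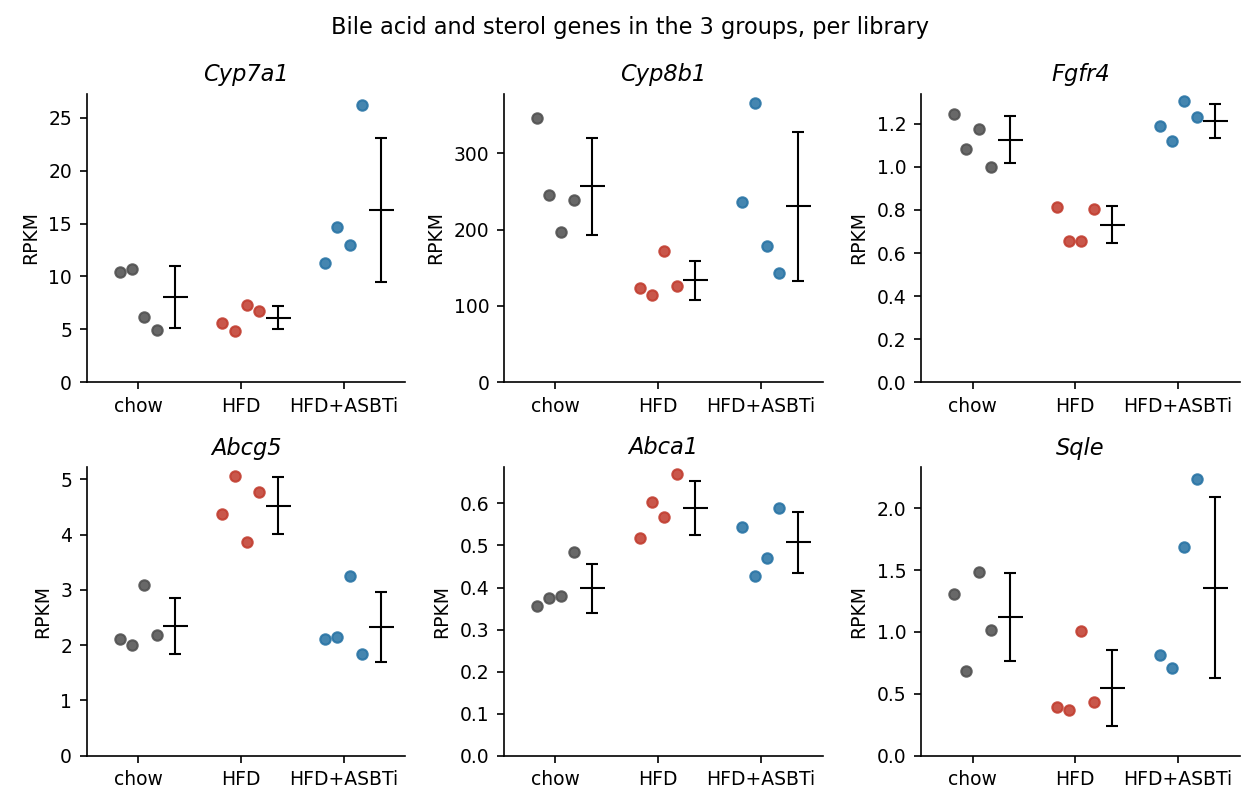
RPKM of 6 bile acid and sterol genes, 1 point per library, with the group mean and SD beside the points (n = 4). Cyp7a1 was above 11 RPKM in every HFD+ASBTi library, and Abcg5 was lower in every HFD+ASBTi library than in any HFD library.

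Cholesterol synthesis and uptake genes were called higher as a list, unevenly across libraries. Camera called the 26 tested SREBP2 targets higher (median log2 change 0.31, adjusted p = 7.11e-07), with adjusted p = 0.586 with an estimated correlation. No member was called by limma over all genes, and 5 were called higher when adjusted over the list alone. Sqle, squalene epoxidase, had 1.36 ± 0.729 against 0.550 ± 0.308 RPKM (SD, n = 4 each; limma adjusted p = 0.434). The list median on the RPM scale, set against the chow mean, was -0.08 and -0.15 in HFD+ASBTi 1 and 2, 0.69 and 0.97 in HFD+ASBTi 3 and 4, and -0.43, -0.64, 0.27 and 0.08 in HFD 1 to 4. These libraries also differed in the clock: Nr1d1, a clock repressor, was at or above 95.0 RPM in HFD+ASBTi 1 and 2 and at 44.9 and 49.0 RPM in HFD+ASBTi 3 and 4. With limma's library weights the list was not called (adjusted p = 0.0567), nor with HFD+ASBTi 3 and 4 left out, where the test pointed lower (0.863).

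Lists of lipid burning and storage and of energy metabolism were called lower in HFD+ASBTi, by small medians and with no called member. Camera called PPARalpha targets lower (34 tested, median -0.19, adjusted p = 3.19e-07), as well as oxidative phosphorylation (44 tested, median -0.06, adjusted p = 8.57e-04), lipid droplet genes (14 tested, median -0.13, adjusted p = 0.0329), ER stress genes (25 tested, median -0.07, adjusted p = 0.0382) and glucose metabolism (16 tested, median -0.11, adjusted p = 0.0445). All 5 had adjusted p = 0.586 with an estimated correlation. No member of these lists was called by limma over all genes, and 0, 0, 0, 0 and 1 were called when adjusted over the list alone. Cidec had 1.01 ± 0.441 against 3.57 ± 1.99 RPKM (SD, n = 4 each; limma adjusted p = 0.406) and was called lower without HFD 1 (0.0292). Cpt1a, Cd36 and Ddit3 had log2 changes of -0.28, -0.28 and -0.10 (limma adjusted p = 0.482, 0.647 and 0.729). The lipid droplet call ended without HFD 2 or 3 or HFD+ASBTi 3 or 4 (adjusted p 0.0656 to 0.325), the ER stress call without HFD 1 or 2 or HFD+ASBTi 2 or 3 (0.0641 to 0.303), and the glucose call without HFD 3 or 4 or HFD+ASBTi 1 or 2 (0.0693 to 0.267). With HFD+ASBTi 1 and 2 both left out, oxidative phosphorylation, ER stress and glucose metabolism were not called (adjusted p = 0.0987, 0.557 and 0.860). With HFD+ASBTi 3 and 4 left out instead, the lipid droplet list was not called and its test pointed higher (adjusted p = 0.691).

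The acute phase list, called lower with the diet, was called higher in HFD+ASBTi than in HFD (23 tested, median 0.44, camera adjusted p = 5.79e-05), with adjusted p = 0.586 with an estimated correlation. Its medians on the RPM scale, from the chow mean, were 0.25, -0.29, -0.75 and 0.28 in HFD+ASBTi 1 to 4 and -0.38, -0.71, -1.03 and -0.49 in HFD 1 to 4, so HFD+ASBTi 3 lay within the HFD values. Male-biased liver genes were higher (19 tested, median 0.31, camera adjusted p = 0.0491), with adjusted p = 0.644 with an estimated correlation. The male-biased call ended without chow 1, 2 or 4, HFD 3 or 4, or HFD+ASBTi 1 or 4 (adjusted p 0.0561 to 0.789), and the test turned to lower without HFD 4 (median 0.03). Circadian clock genes were lower (15 tested, median -0.23, camera adjusted p = 0.00181), with adjusted p = 0.586 with an estimated correlation. The clock change moved with HFD+ASBTi 1 and 2, where Arntl was at 3.08 and 3.82 RPM against 0.669 and 0.543 RPM in HFD+ASBTi 3 and 4. With those 2 libraries left out the clock list was not called (adjusted p = 0.974). In these 3 lists no member was called by limma over all genes, and none when adjusted over the list alone.

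The other lists were not called in HFD+ASBTi against HFD. Macrophage markers had a median of 0.19 (12 tested, adjusted p = 0.0815), and the list was called without chow C7, HFD 4 or HFD+ASBTi 3 (adjusted p 0.00540 to 0.0343). Interferon-stimulated genes had a median of 0.03 (13 tested, adjusted p = 0.655), with 1 called when adjusted over the list alone, and were called without HFD 1 (adjusted p = 0.0401). Hepatocyte markers had a median of 0.12 (19 tested, adjusted p = 0.0659), and were called without HFD 1, HFD 4 or HFD+ASBTi 3 (0.00336 to 0.0270). CAR and PXR targets had a median of -0.12 (18 tested, adjusted p = 0.0899), and were called without HFD 4 or HFD+ASBTi 3 (0.00222 to 0.0245). Fatty acid synthesis and LXR targets had medians of -0.07 each (adjusted p = 0.157 and 0.0899), with 1 and 3 called when adjusted over the list alone, and both were called without HFD+ASBTi 3 (0.00109 and 0.0454). Adipose markers and fibrosis genes had medians of -0.65 and -0.19 (adjusted p = 0.219 and 0.126), with 2 and 0 called when adjusted over the list alone, and both were called without HFD 1 (0.0296 and 0.00629). NRF2 targets had a median of -0.07 (adjusted p = 0.0899) and were called without HFD+ASBTi 2 (0.0277). Lipoprotein genes, cell cycle genes, endothelial markers, red blood cell markers and cytokines had medians of -0.03, -0.10, 0.08, 0.05 and 0.01 (adjusted p = 0.476, 0.272, 0.637, 0.845 and 0.655), and the cytokine test pointed lower. Of the cell cycle genes 3 were called when adjusted over the list alone, and of the pancreas and intestine markers 1 of 2. The 3 female-biased genes and the cholangiocyte marker tested were not called. Fasn, Scd1 and Cd68 had log2 changes of -0.07, -1.04 and 0.05 (limma adjusted p = 0.983, 0.594 and 0.954). Mean RPKM in HFD+ASBTi of the panel genes below the filter was 0.242 for Slc10a2, 0.11 for Pparg, 0.0844 for Tnf, 0.418 for Ccl2 and 0.0686 for Col1a1.

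Of the 766 genes called between HFD and chow, 5 were called the opposite way with the inhibitor. Maff, Pla2g6 and 4931408D14Rik had risen with the diet, 1.75-fold, 2.76-fold and 5.12-fold (limma adjusted p = 0.0140, 3.00e-04 and 7.03e-04), and Fgfr4 and Bmp1 had fallen, 1.54-fold and 1.89-fold (limma adjusted p = 0.00492 and 0.00145). Independent lists of these sizes would share 0.395 genes in opposite directions. The change with the inhibitor had the opposite sign to the diet change for 642 of the 766 genes (83.8%), with a correlation across genes of -0.592 and a covariance of -0.140. Both comparisons share the HFD libraries. In 100 simulations of unchanged groups the median correlation was -0.462 (-0.902 to 0.758), the covariance -0.0135 (-0.0470 to 0.00887) and the opposite share 65.5% (21.9% to 84.9%). The observed correlation and opposite share lay within these ranges and the observed covariance outside its range. The 766 genes were picked for a diet change that these simulations lacked, so that covariance is no evidence of a return. In 100 simulations that kept the diet change and gave the inhibitor no effect, the median covariance was -0.0721 (-0.150 to 0.0182), the opposite share 67.0% (40.3% to 82.5%), and 0 genes returned (0 to 3); the observed covariance lay within its range, and the observed opposite share and the 5 returned genes lay above theirs. With the HFD libraries split 2 and 2 between the comparisons, 0 to 2 genes returned over the 6 assignments. The opposite share was then 62.6% to 79.7%, below the observed 83.8%. The simulations shared all HFD libraries between the comparisons and were not run with the split, so their ranges cannot be set against these values. The correlation was -0.479 to -0.173 and the covariance -0.167 to -0.0765. The number returned was 1 without chow 2, chow 4, HFD 1, HFD 2 or HFD 3, 3 without chow C7 or HFD 4, 9 without HFD+ASBTi 3, and 0 by limma without HFD+ASBTi 1, 2 or 4. It was 0 by limma with HFD+ASBTi 1 and 2 left out together and 74 with HFD+ASBTi 3 and 4 left out.

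**Figure D4:**
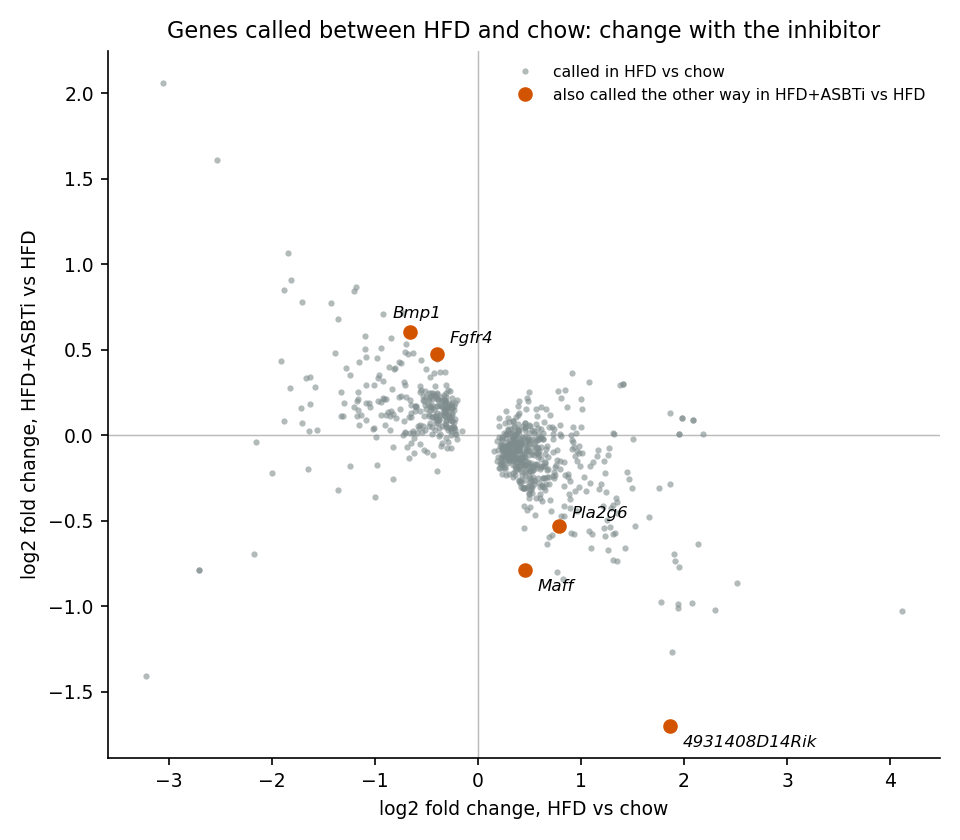
Log2 fold change of HFD against chow (x) and of HFD+ASBTi against HFD (y) for the 766 genes called between HFD and chow, 1 grey point per gene, on the log2(RPKM + 0.5) scale. The 5 orange points are genes also called the opposite way with the inhibitor, and 642 of the 766 genes have opposite signs on the axes, which share the HFD libraries.

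Against chow, HFD+ASBTi livers held less RNA of several drug-metabolising enzymes. Cyp3a11 was 26.5-fold lower at 3.48 ± 1.60 against 92.3 ± 15.5 RPKM (SD, n = 4 each; limma adjusted p = 2.25e-04). Camk2b, a calcium-dependent kinase, was 7.91-fold lower at 1.53 ± 1.36 RPKM (limma adjusted p = 0.00206), or 13.65-fold without HFD+ASBTi 3. Apoa4 was 9.39-fold higher at 479 ± 274 RPKM, Serpina7 was 6.22-fold higher at 7.34 ± 3.32 RPKM, and Srebf1 was 3.05-fold higher at 4.94 ± 2.27 RPKM (limma adjusted p = 0.00431, 0.00814 and 0.00886). Cyp7a1 had 16.3 ± 6.78 against 8.07 ± 2.92 RPKM and did not pass the test (limma adjusted p = 0.0717). Cyp4a14, a fatty acid hydroxylase, was 4.38-fold lower and Igfbp1, a secreted binding protein of insulin-like growth factors, 5.66-fold lower (limma adjusted p = 0.0356 and 0.0410), the latter 3.62-fold without chow C7. The Cyp4a14 call ended without chow 2, C7 or 4 or HFD+ASBTi 1 or 3 (adjusted p 0.0503 to 0.0853), and the Igfbp1 call without chow 1, 2 or C7, HFD 2 or 3, or HFD+ASBTi 1, 2 or 3 (0.0562 to 0.0959). The Mir1906 entries were at 0.846 ± 1.07 RPKM against 11.2 ± 0.474 RPKM (limma adjusted p = 0.0215), a call on few reads that ended without chow 1, 2 or C7 (0.0517 to 0.0582).

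Of 18 tested CAR and PXR targets, 6 fell and 12 were not called, with 8 called when adjusted over the list alone (median -0.70, camera adjusted p = 4.17e-07), with adjusted p = 0.266 with an estimated correlation. Gadd45b fell 5.81-fold and Cyp3a25 3.12-fold (limma adjusted p = 3.88e-04 and 0.00582). Of 25 tested ER stress genes, 6 fell and 19 were not called, with 7 called when adjusted over the list alone (median -0.06, camera adjusted p = 3.40e-04), with adjusted p = 0.635 with an estimated correlation. Herpud1, which acts in the disposal of misfolded proteins, fell 1.88-fold to 19.0 ± 6.25 RPKM (limma adjusted p = 0.0167), a call that ended without chow 2 (0.0504). Hepatocyte markers were lower as a list (19 tested, 1 fell, 1 called when adjusted over the list alone, median -0.17, camera adjusted p = 0.0136), with adjusted p = 0.737 with an estimated correlation. The member that fell was Hnf4a, 1.44-fold to 13.3 ± 0.921 RPKM (SD, n = 4; limma adjusted p = 0.0155). Of 16 tested glucose metabolism genes 1 rose and 4 fell, with 5 called when adjusted over the list alone (median -0.00, mean -0.47, adjusted p = 0.111), and the list was called without chow C7 or HFD+ASBTi 3 (0.0352 to 0.0438).

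Of 13 tested interferon-stimulated genes, 5 rose and 8 were not called, with 12 called when adjusted over the list alone (median 0.71, camera adjusted p = 4.17e-07), with adjusted p = 0.590 with an estimated correlation. Psmb8 rose 1.76-fold to 4.71 ± 0.404 RPKM and Stat2, a mediator of interferon signals, rose 1.60-fold to 2.40 ± 0.274 RPKM (SD, n = 4; limma adjusted p = 0.00691 and 0.00467). Macrophage markers were higher as a list (12 tested, 2 rose, 2 called when adjusted over the list alone, median 0.36, camera adjusted p = 0.0182), with adjusted p = 0.753 with an estimated correlation. Mpeg1, a macrophage pore-forming protein, rose 2.47-fold to 15.4 ± 5.0 RPKM and Cd68 rose 1.99-fold to 2.15 ± 0.333 RPKM (limma adjusted p = 0.0174 and 0.0251). The Mpeg1 call ended without chow 2 (0.0554) and the Cd68 call without chow 1, 2 or 4 or HFD+ASBTi 2 (0.0607 to 0.0748). The macrophage call ended without chow 1, chow 2 or HFD+ASBTi 2 (adjusted p 0.0758 to 0.114), and with HFD+ASBTi 1 and 2 both left out (0.251); HFD+ASBTi 2 had the highest macrophage and interferon medians of the group. Of 6 tested red blood cell markers, the 4 globin entries rose, with 4 called when adjusted over the list alone (median 1.96, camera adjusted p = 0.00290), with adjusted p = 0.635 with an estimated correlation. On the RPM scale, with 5 members and without Hbb-b1 and Hbb-b2, the list medians from the chow mean were 0.15 to 0.37 in the HFD+ASBTi libraries. Hbb-b1, Hbb-b2 and the entries Hbb-bs and Hbb-bt, which share their reads, were 3.91-fold, 3.81-fold, 3.91-fold and 3.81-fold higher (limma adjusted p = 0.0194 for each), calls that ended without chow 1, chow 2 or HFD+ASBTi 2 (0.0504 to 0.0538). Hba-a1 and Hba-a2, which also share reads, rose 3.39-fold for Hba-a1 (limma adjusted p = 0.0224), and these calls ended without chow 1, chow 2, chow C7, HFD+ASBTi 1 or HFD+ASBTi 2 (0.0525 to 0.0635). Without chow 4 the folds were 6.29 for Hbb-b1 and Hbb-bs, 6.04 for Hbb-b2 and Hbb-bt, and 5.42 for Hba-a1.

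Of 19 tested fatty acid synthesis genes, 2 rose and 17 were not called, with 3 called when adjusted over the list alone (median 0.34, camera adjusted p = 0.0440), with adjusted p = 0.753 with an estimated correlation. The list's call ended without chow 2, chow C7, HFD 4 or HFD+ASBTi 3 or 4 (adjusted p 0.0510 to 0.321). Of 5 tested adipose markers, 2 rose, with 3 called when adjusted over the list alone (median 0.62, camera adjusted p = 0.0440), with adjusted p = 0.635 with an estimated correlation. Adrb3, the fat cell beta-adrenergic receptor, rose 2.74-fold to 4.41 ± 0.926 RPKM (SD, n = 4; limma adjusted p = 0.00462). The adipose call ended without chow 1, 2 or 4, HFD 4, or HFD+ASBTi 1 or 2 (adjusted p 0.0555 to 0.0836). Of 14 tested lipid droplet genes 4 rose and 1 fell, with 7 called when adjusted over the list alone (median 0.32, adjusted p = 0.135), and the list was called without HFD+ASBTi 3 (0.0414). Fitm1 and G0s2, which act in lipid storage, rose 2.30-fold and 2.77-fold (limma adjusted p = 0.0125 and 0.0145). Cd36 rose 3.18-fold (limma adjusted p = 0.0202), a call that ended without chow 1, chow 2, HFD+ASBTi 1 or HFD+ASBTi 2 (0.0523 to 0.0620). Fabp2 and Cela2a, both tested members of the pancreas and intestine list, rose 2.43-fold and 1.52-fold (limma adjusted p = 0.00440 and 0.00799), with 2 called when adjusted over the list alone.

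The other lists were not called in HFD+ASBTi against chow. SREBP2 targets had a median of 0.24 (26 tested, 2 rose, 2 called when adjusted over the list alone, adjusted p = 0.116), and were called without chow 1, chow 4 or HFD+ASBTi 1 or 2 (0.00458 to 0.0389). Acute phase genes had a median of -0.16 (23 tested, adjusted p = 0.111), and were called without HFD+ASBTi 1 or 4 (0.00411 to 0.0139). Bile acid synthesis genes had a median of 0.05 and a mean of -0.02, with the test direction lower (17 tested, 1 fell, 3 called when adjusted over the list alone, adjusted p = 0.319). Bile acid transport and FXR signalling genes had a median of 0.00 (12 tested, 1 fell, 1 called when adjusted over the list alone, adjusted p = 0.295). PPARalpha targets had a median of -0.05 (34 tested, 2 rose, 2 fell, 8 called when adjusted over the list alone, adjusted p = 0.371), LXR targets of 0.17 (adjusted p = 0.136), and lipoprotein genes of 0.09 (16 tested, 3 rose, 4 called when adjusted over the list alone, adjusted p = 0.630). Oxidative phosphorylation and fibrosis genes had medians of 0.00 and 0.02 with the test direction lower (adjusted p = 0.236 and 0.292), with 0 and 1 members called lower by limma, and the former was called without chow C7 or HFD+ASBTi 3 (0.0216 to 0.0399). Clock, male-biased, NRF2, cytokine, endothelial and cell cycle lists had medians of 0.10, 0.31, -0.05, 0.18, -0.18 and 0.04 (adjusted p = 0.371, 0.448, 0.291, 0.448, 0.295 and 0.995). In these 6 lists limma called 1, 4, 1, 0, 0 and 0 members, and 1, 5, 3, 0, 0 and 0 were called when adjusted over the list alone. The 3 female-biased genes and the cholangiocyte marker tested were not called.

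In the panel, Sqle had a log2 change of 0.14 from chow (limma adjusted p = 0.812). Cyp8b1, Cyp7b1, Nr0b2, Abcb11 and Slc10a1 had -0.22, 0.16, -0.01, -0.02 and 0.01 (limma adjusted p = 0.687, 0.742, 0.980, 0.930 and 0.977). Fasn, Scd1, Abcg5, Abca1, Cidec, Cpt1a and Ddit3 had 0.87, 0.15, -0.02, 0.17, 0.62, 0.01 and -0.02 (limma adjusted p = 0.301, 0.892, 0.968, 0.193, 0.393, 0.984 and 0.933).

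In all, limma called 446 of 6325 genes between HFD+ASBTi and chow, 300 higher and 146 lower, and 1474 had an unadjusted p under 0.05. Camera called 8 of 25 lists, 5 higher and 3 lower. In the authors' deposited table, 4014 of 27035 transcripts had an unadjusted p under 0.05 for this ratio. The higher and lower counts were 224 and 186 with median-of-ratios scaling, 163 and 162 with equal RPKM sums, and 190 and 203 with quantile normalization. The count of genes was 224 without chow 1, 142 without chow 2, 232 without chow C7, 276 without chow 4, 230 without HFD+ASBTi 1 and 228 without HFD+ASBTi 2, and 5 lists were called without chow 2. Of the 766 genes called between HFD and chow, 320 were called in the same direction here, 211 higher and 109 lower. Independent lists would share 29.5 in the same direction. The log2 changes of the 766 genes correlated at 0.935 across genes, with a covariance of 0.503. Both comparisons share the chow libraries. Simulated unchanged groups shared 0 genes, but at most 1 and 6 genes were called in their comparisons. That 0 therefore cannot show how much of the 320 comes from the shared libraries. Their median correlation was 0.540 (-0.379 to 0.945), a range that holds the observed one. Their median covariance was 0.0162 (-0.00475 to 0.0447), a range that does not. The 766 genes were picked for their change between HFD and chow, which these simulations lacked. That covariance therefore cannot show how much comes from the shared libraries either. In simulations that kept the diet change and gave the inhibitor no effect, the median number shared was 566 (335 to 1121), above the 320 observed. These simulations also called a median of 806 genes (378 to 1737) in HFD+ASBTi against chow, against the 446 observed. The lower number shared therefore cannot be read apart from the lower number called. With the chow libraries split 2 and 2 between the comparisons, 36 to 72 genes were shared over the 6 assignments, with a correlation of 0.854 to 0.927 and a covariance of 0.637 to 0.872.

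**Figure D5:**
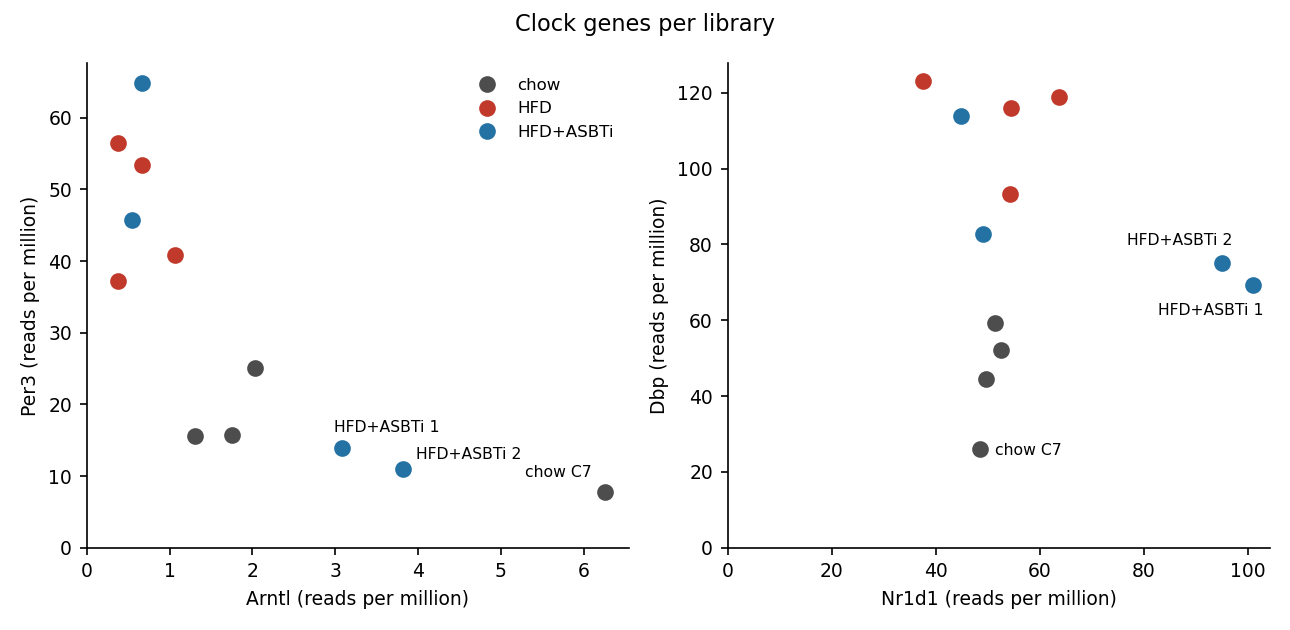
RPM of Arntl against Per3 and of Nr1d1 against Dbp, clock genes, with 1 point per library coloured by group. Chow C7 and HFD+ASBTi 1 and 2 have the highest Arntl, at 6.25, 3.08 and 3.82 RPM, and HFD+ASBTi 1 and 2 the highest Nr1d1.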

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

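All tests of explanations and all counts over other splits in this part were chosen only after the results were seen.

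For the genes called, no other split of the 8 libraries of a comparison gave as many. In each comparison 1 of 35 splits, the real 1, reached the count, the smallest share that 35 splits can give. Chance is unlikely at that level in this fit, with no correction for the number of counts tested. The real count was 766 against at most 3 in HFD against chow, 6 against at most 4 in HFD+ASBTi against HFD, and 446 against at most 3 in HFD+ASBTi against chow. The margin of 6 over 4 is narrow, and the count depends on the setting. Several other settings called 0 to 3 genes there, while library weights called more and the fit without HFD+ASBTi 3 called 9. Splits were run in the main fit alone, so these counts have no splits of their own to be set against. Chance therefore stays open for that comparison. For the 5 genes returned toward chow, 1 of 70 assignments reached the count and the highest other was 2. They are 5 of the 6 genes called in HFD+ASBTi against HFD, so this is not separate evidence. Several other settings gave 0 to 2 returned genes and the fit without HFD+ASBTi 3 gave 9, so chance stays open here as well. For the gene lists called, chance cannot be excluded: 6 of 35 splits reached 10 lists in HFD against chow (highest other 12), 12 of 35 reached 9 in HFD+ASBTi against HFD (highest other 12), and 13 of 35 reached 8 in HFD+ASBTi against chow (highest other 11).

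Circadian clock genes were lower as a list in HFD+ASBTi than in HFD (camera adjusted p = 0.00181, and 0.586 with an estimated correlation). A difference in scaling between libraries argues little here, since the groups' mean log2 scaling factors differed by 0.013. If livers were at different clock phases, genes driven through ROR elements would move against the rest of the clock, and they did: 4 of 4 such members were above 0 (median log2 change 0.33 on the RPM scale), while 15 of the other 16 were below 0 (median -0.35). A difference in clock phase may therefore underlie the list change, but it is carried by HFD+ASBTi 1 and 2. The log2 level of these members minus the rest was -1.28 and -1.24 there and -3.43 to -2.59 in HFD. It was -3.49 and -2.94 in HFD+ASBTi 3 and 4, which had the inhibitor too, so the inhibitor did not bring this level in every library. Chow 1, 2 and 4 were at -1.94, -2.21 and -2.42 and chow C7 at -0.86, all above every HFD library. The chow mice had another diet, so their values cannot tell what the inhibitor did. The labels give no collection time, and their identifiers place HFD+ASBTi 1 and 2 in another number run than the other HFD and HFD+ASBTi libraries, so a difference in handling stays open as well.

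Interferon-stimulated genes were higher as a list in HFD than in chow (camera adjusted p = 1.85e-05, and 0.442 with an estimated correlation). On the RPM scale 27 of 27 members were above 0, but members move together (estimated correlation 0.476 among those tested). A proportional rise of macrophages is argued against only in part. The median log2 change of 25 macrophage markers was 0.15 against 0.89 for the interferon list, a difference of -0.74. Its SE of 0.17 treats genes as independent and does not measure the spread between libraries. Chow C7 lowers the macrophage change, with a median from the chow mean of 0.65 against -0.36, -0.2 and 0.07 in chow 1, 2 and 4. Without chow C7 the macrophage list was called higher (camera adjusted p = 0.00654). In each HFD library the macrophage median (-0.02 to 0.45) lay below the interferon median (0.55 to 1.09). Scaling is argued against as well, since the groups' mean log2 factors differed by 0.033. Interferon signalling in resident liver cells may underlie the rise, a hypothesis that was not tested, and activated or infiltrating immune cells stay open. The diet itself is the difference the design names, and the step between diet and interferon was not tested.

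Adipose tissue markers were higher as a list in HFD than in chow (camera adjusted p = 0.0102, and 0.442 with an estimated correlation). Fat carried along with the liver would bring its abundant transcripts, and Adipoq rose by a share of only 0.039 of the rise of Cfd and 0.00754 of the rise of Cidec. Mean RPM in HFD and chow was 0.505 and 0.244 for Adipoq, 7.04 and 0.343 for Cfd, 39.7 and 5.07 for Cidec, 5.76 and 3.53 for Fabp4, and 0.121 and 0.199 for Plin1. Adipoq was at 1.85 RPM in HFD 2 and 0.974 RPM in chow C7, libraries where Cfd was the highest of its group (11.7 and 1.28 RPM), so some fat carried along stays open there; in HFD 3, Cfd was at 11.4 RPM with Adipoq at 0.167 RPM, and Adipoq was listed at 0 in HFD 1 and 4. Carried-along fat is therefore argued against only as the whole cause, and expression of Cidec and Cfd by lipid-laden hepatocytes may contribute, a hypothesis from these same data.

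Of 285 sets of 4 values, each of a named gene or a library measure in 1 group, 14 had 1 library far from the other 3. Chance picks out about 1 in 20, or 14.2, but entries that share reads are not independent sets. Abcg8 was at 4.33 RPKM in chow 4 (others 2.92 to 3.14) and at 4.59 in HFD 3 (6.42 to 6.6). Ccnd1 was at 6.87 in HFD 4 (1.54 to 2.14). Cfd was at 0.731 in chow C7 (0 to 0.0511). Enho was at 1.99 in HFD 4 (0.309 to 0.494) and at 6.79 in HFD+ASBTi 4 (2.14 to 2.43). Hnf4a was at 13.7 in HFD 1 (10.4 to 10.7). Mir1906-1 and Mir1906-2 were both at 7.27 in HFD 2 (0 to 1.19). Plin5 was at 2.31 in HFD 1 (3.28 to 3.44). Scd1 was at 93.6 in chow C7 (193 to 208). Scp2 was at 17.1 in HFD 1 (19.5 to 20). Sqle was at 1.01 in HFD 3 (0.367 to 0.431). Srebf1 was at 10.3 in HFD 1 (9.73 to 9.79).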

How the results depend on the processing

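Of the alternatives, 7 were chosen only after the results were seen: the RPM scale, the transcript with the lowest mean per gene, 1 gene per set of identical values, a minimum genomic span, leaving out HFD+ASBTi 1 and 2 with or without chow C7, and leaving out HFD+ASBTi 3 and 4 instead. Chow C7 and HFD+ASBTi 1 and 2 were picked for their high Arntl, so these fits say nothing independent about the clock. The causes of the changes below were not tested.

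Requiring an absolute log2 fold change of at least 1 left 128 genes in HFD against chow, 1 in HFD+ASBTi against HFD, 76 in HFD+ASBTi against chow and 1 returned gene. With a correlation estimated per list, camera called 0 lists in each comparison (smallest adjusted p = 0.442, 0.586 and 0.266). For HFD+ASBTi against HFD and for the genes returned, limma called 2 and 2 with a pseudocount of 1, 0 and 0 with no filter on low values, 1 and 1 with a mean RPKM of at least 1, 2 and 2 with equal RPKM sums, and 3 and 1 in a fit of the 2 groups alone, where 1 gene was shared with the 6. Quantile normalization gave 3 returned genes, and the filter at a mean RPKM of at least 1 gave 4 lists in HFD+ASBTi against HFD. With library weights (arrayWeights) the counts were 1592, 16 and 1031 genes, and 14 returned.

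On the RPM scale 12017 genes passed the filter, against 6325 in the main fit. There limma called 1270 genes in HFD against chow and 704 in HFD+ASBTi against chow, and camera 14 lists in HFD+ASBTi against HFD. These gene counts are over more genes, so they do not show that a larger share changed. With HFD+ASBTi 1 and 2 left out, limma called 0 genes in HFD+ASBTi against HFD, 256 in HFD+ASBTi against chow and 0 returned, and camera 5 lists in HFD+ASBTi against HFD. With chow C7 left out as well, these were 0, 128, 0 and 4. With HFD+ASBTi 3 and 4 left out, limma called 121 genes in HFD+ASBTi against HFD and 74 returned, so the 2 pairs of HFD+ASBTi libraries differ widely in how many genes they call.

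Some lists changed direction. In HFD against chow the fibrosis list, whose test pointed lower, was called higher with no filter on low values (median 0.0653, adjusted p = 0.0284) and on the RPM scale (median 0.41, adjusted p = 0.0417). The main filter left 9 of its 38 members, and the RPM scale held 30, so members and scale changed at once. In HFD+ASBTi against HFD the male-biased list pointed lower without HFD 4 (median 0.0335, adjusted p = 0.789; medians 0.0335 to 0.457 over the fits without 1 library). The clock list there had a median of -0.0018 with chow C7 and HFD+ASBTi 1 and 2 left out (adjusted p = 0.985). With HFD+ASBTi 3 and 4 left out, the tests turned to lower for the SREBP2 list (median 0.0881, adjusted p = 0.863) and to higher for the lipid droplet list (median 0.014, adjusted p = 0.691).

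Over the 12 fits that each left out 1 library, genes called ranged from 458 to 864 in HFD against chow, 0 to 9 in HFD+ASBTi against HFD and 142 to 521 in HFD+ASBTi against chow. Lists called ranged from 10 to 13, 6 to 13 and 5 to 10, and genes returned from 0 to 9. Over these fits and the alternatives chosen earlier, the fold minimum and the list correlation left aside, 43 of 62 named genes called in HFD against chow kept their call wherever they were tested, 16 of 38 in HFD+ASBTi against chow and 0 of 6 in HFD+ASBTi against HFD. Called lists did so in 8 of 10 cases in HFD against chow, 5 of 8 in HFD+ASBTi against chow and 3 of 9 in HFD+ASBTi against HFD, while none kept its call with the list correlation.

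With libraries of the same number treated as a block, limma called 3 genes in HFD+ASBTi against HFD, of which 0 were among the 6. Deviations from the group means correlated across genes at 0.0408 to 0.0691 between same-numbered HFD and HFD+ASBTi libraries. By this measure 3 of 8 libraries correlated best with their own number, so the numbers gave no ground for pairing. Depth limits genes with few reads, such as the Mir122a and Mir1906 entries, more than the abundant ones.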

Other observations

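The alternatives that left out HFD+ASBTi 1 and 2 or HFD+ASBTi 3 and 4 were chosen only after the results were seen.

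In HFD+ASBTi, the list of SREBP2 targets and the clock differed between the same libraries. The SREBP2 list median on the RPM scale, from the chow mean, was -0.08 and -0.15 in HFD+ASBTi 1 and 2 and 0.69 and 0.97 in HFD+ASBTi 3 and 4, and Per3, a clock repressor, was at 13.9 and 11.0 RPM and at 64.8 and 45.7 RPM. Time of collection could contribute to this spread; with HFD+ASBTi 1 and 2 left out, 5 lists were called in HFD+ASBTi against HFD, and with HFD+ASBTi 3 and 4 left out, 11. Cyp7a1 was above every HFD library in all 4 HFD+ASBTi libraries, and so necessarily in each pair, but did not pass the test over all genes.

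A second test of the inhibitor on livers with a recorded collection time would separate clock phase from its effect on sterol genes.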
